A study of Saccharomyces cerevisiae with 8 samples.

How the data were processed

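Messenger RNA of budding yeast (Saccharomyces cerevisiae) was sequenced from a wild-type strain (WT, WFA72) and a strain with the genotype mec1 (WFA73), per the labels. MEC1 encodes a checkpoint kinase, the yeast counterpart of ATR. Cells were sampled in alpha factor (G1), after 1 h in 200 mM hydroxyurea (HU), and 30 or 60 min after the drug had been filtered away (R30 and R60), per the labels' protocols. Total RNA was isolated with hot phenol and the libraries were made with the Illumina TruSeq Stranded mRNA kit, per the labels, and read on a MiSeq as pairs of 75 bp, per the series description. Each strain and time has 1 library, so there are 8 libraries and no replicates.

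Reads were aligned with BWA to the sacCer3 genome, per the submitters' processing notes, which give no version. The header of the deposited table calls its values log2-transformed RPKM, but the numbers are neither log-transformed nor divided by gene length. Within each library, each value multiplied by a whole number of windows is a whole multiple of 1 step, to within 0.00574 of a step in all 8 libraries. The deposited values are therefore read here as RPM (reads scaled to a common total per library), averaged over the windows of the genome that touch a gene. The number of windows predicted from a gene's body and a flank of 1000 bp on either side matched the table exactly for 6326 of 6547 features (96.6%), and 221 features had fewer windows. A feature had a median of 5 windows (1 to 12), and reads of a neighbour inside those windows count towards it, on either strand as far as the table shows. The correlation between neighbouring features along the chromosomes was 0.676. The size of the step gives the number of reads behind the RPM scale of each library, from 1596132 (WT HU) to 3935979 (mec1 G1).

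Because the values are not read counts of genes, the count-based test named in the analysis plan was replaced by the plan's test for normalised values. Values were put on the scale log2(value + 1), and features with a value of 1 or more in at least 2 libraries were kept, which left 6504 and removed 43. A linear model with strain and time as additive terms was fitted with limma 3.58.1 in R 4.3.3, with a mean-dependent prior variance, 3 residual and 3.82 prior degrees of freedom. P-values were adjusted with the Benjamini-Hochberg method and called under 0.05, two-sided. The 5 tested contrasts were HU minus G1, R30 minus HU, R60 minus HU and R60 minus G1, each over both strains, and mec1 minus WT over the 4 times. With no replicates, the p-values measure a shared change against how unevenly the strains moved over the times in this additive model, and not against the spread between cultures. In simulated data on 6504 genes with 100 changed genes per size, a change of 1 on the log2 scale was recovered for 67 genes and a change of 2 for 83 genes in HU minus G1 with 11 false calls. In mec1 minus WT, the numbers were 84, 92 and 7. The simulated noise was independent between genes and libraries, so these numbers do not cover deviations that many genes of a library share.

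Differences between single libraries and the strain difference of a response (the mec1 change minus the WT change) have no replicate and were not tested. They are given as log2 differences, with 95% intervals that take the mean reads per window as the count and cover counting error only. The reads in the libraries carry no molecular identifiers, so these are not intervals for independent molecules. The median of the mean reads per window was 94.2 in WT HU, the library with the fewest reads, and 256 in mec1 G1, the one with the most.

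In the table, 27 gene lists were looked up and 26 had tested members. The lists were checkpoint kinases and adaptors, DNA damage induced genes, G1/S genes, histone genes, G2/M genes, M/G1 genes, pheromone response genes, alpha mating type genes, meiosis genes, the iron regulon, copper homeostasis, the general stress response, heat shock genes, oxidative stress genes, ribosomal protein genes, ribosome biogenesis, the proteasome, phosphate starvation, amino acid biosynthesis, sulphur assimilation, the nuclear respiratory chain and ATP synthase, mitochondrially encoded genes, glycolysis, hexose transporters, ergosterol biosynthesis, seripauperins and strain markers. The ribosomal protein list was drawn by gene name and so also holds RPP1, which encodes a subunit of RNase P. The table covers 16 chromosomes and holds 0 of the 8 mitochondrially encoded genes. Lists were tested with camera in limma with a preset inter-gene correlation of 0.01, adjusted over 130 tests (26 lists in 5 contrasts), and again with an estimated correlation and with fry. For single libraries, a list's median is given with its percentile among 10000 random lists of the same size, matched on mean value within 50 ranks on either side. The genes named were, for each tested contrast, up to 10 with the largest positive and 10 with the largest negative fitted change among those called and moving the same way in every pair. For the strain difference of the HU response they were the 10 largest in each direction among the 75% of genes with the highest mean, with a counting interval that leaves out 0. MEC1, SML1, RNR1 to RNR4 and HUG1 were named in every library, and each list gave its 4 largest changes. The contrasts, the test, the lists and this rule were set before the data were examined.

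Gene names were matched to the RefSeq R64 annotation for 5902 features, by locus tag (1415), symbol (4396) or synonym (91), and 645 were not matched. The starts in the table equalled those of R64 for 991 features (16.8%), so the table uses other gene positions, and the coordinates given are those of the table. The median shift from the R64 start was −355 bp on chromosome XI, −84 bp on X and −6 to 5 bp on the others. On XI, the deposited spread over a gene's windows correlated at a median of 0.854 with that predicted from R64 positions, against 0.707 from the table's positions. Windows on X and XI are therefore displaced from the R64 genes. To separate neighbours, the windows of each chromosome were written as sums of transcripts at the R64 positions, with assumed ends of 50 bp upstream and 100 bp downstream, and solved by non-negative least squares (scipy 1.17.1, numpy 2.4.6, pandas 2.3.3, Python 3.11.15). These neighbour-separated values were chosen after seeing the data and serve as a check, not as a measurement. In a simulation, a log2 change of 1 came out at a median of 0.69 in the window means and 1.01 in the separated values. A change of 2 came out at 1.24 and 1.98. Of 4709 unchanged genes, 19 in the window means and 23 in the separated values had a size of 1 or more. The simulation started from mec1 G1, the library with the most reads, and scored only transcripts with 50 or more reads. It does not cover weaker genes or libraries with fewer reads, such as WT HU. In the real data, 41 of 6504 features differed by 2-fold or more between the G1 libraries, and 301 of 5550 with neighbours separated. The simulated reads followed the same positions, ends and even coverage that the separation assumes. The simulation therefore checks the solution of the sums and cannot check those assumptions. Figures were drawn with matplotlib 3.10.9.

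The alternatives tried were limma without the mean-dependent prior, quantile normalization, no filter on low values, a pseudocount of 0.1, leaving out the 10 genes with the highest mean, a threshold of 0.01, only the 4 libraries of the times compared, leaving out each time in turn, and no term for time. Alternatives that need read counts per gene were not applicable.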

Results

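Gene expression was measured by mRNA sequencing in wild-type (WT) and mec1 yeast before, during and after replication stress. Mec1 is the kinase that starts the S-phase checkpoint, and hydroxyurea inhibits ribonucleotide reductase (RNR), the enzyme that makes deoxyribonucleotides. The 8 libraries are 1 per strain at each of 4 times: arrest in G1 with the mating pheromone alpha factor (G1), 1 h in 200 mM hydroxyurea after release (HU), and 30 or 60 min after its removal (R30 and R60). There is no replicate of any strain and time. The RPM scale of the libraries rests on 2417698, 1596132, 1820129 and 3101748 reads in WT (G1, HU, R30, R60) and on 3935979, 2757721, 2441751 and 3428029 reads in mec1. The table gives 6547 features, and the 10 with the highest values held 3.09% (WT R60) to 5.11% (mec1 HU) of the summed values. Across genes, which are not independent replicates, the G1 libraries of the strains correlated at 0.988 and mec1 R30 with mec1 R60 at 0.990, while the lowest correlation, 0.927, was that of WT G1 with mec1 HU.

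The feature of the gene named in the genotype, MEC1 (chromosome II, 505662 to 512768), had values of 36.2, 90.3, 35.7 and 38.7 RPM in WT and 77.1, 124, 83.9 and 76.6 RPM in mec1 at G1, HU, R30 and R60. It shares windows with CKS1 and YBR137W, and the neighbour-separated MEC1 value was at most 5.31 RPM in WT, which carries the gene, and 53.8 to 59.3 RPM in mec1. The separation therefore does not resolve MEC1, and it cannot check which libraries carry the mutation. HUG1, a small inhibitor of RNR induced by the checkpoint, was at 445 RPM in WT HU and 37.7 RPM in mec1 HU. RNR2 and RNR4, which encode the small RNR subunit, were at 2069 and 2467 RPM in WT HU and at 310 and 408 RPM in mec1 HU.

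**Figure D1:**
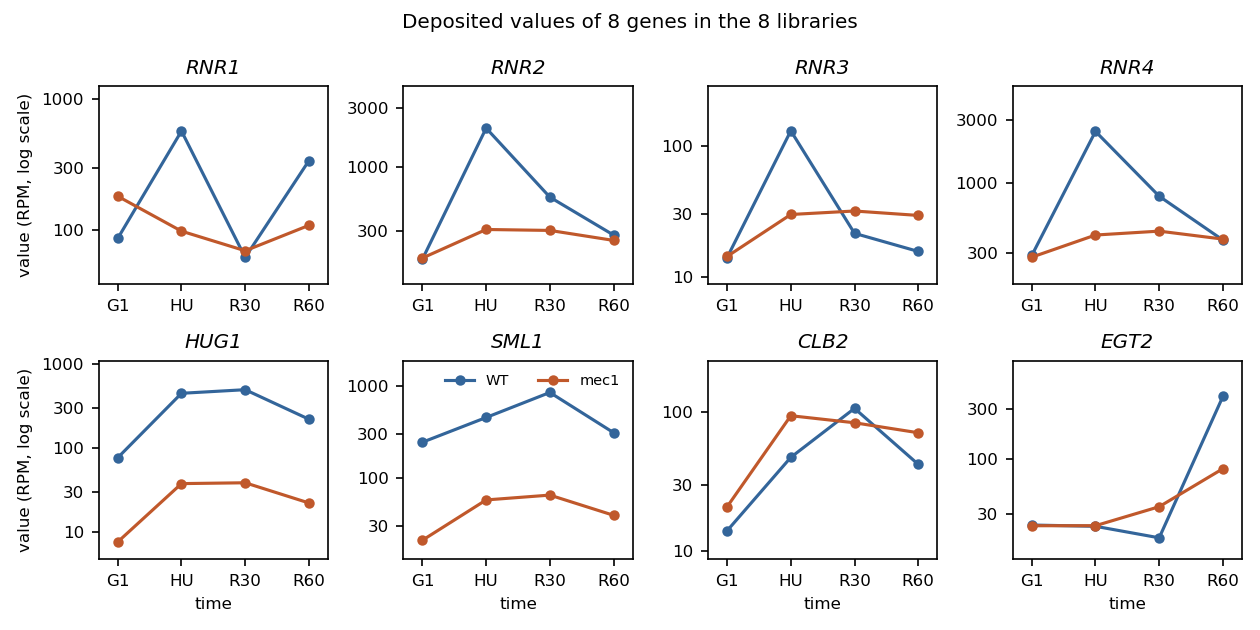
Deposited values in RPM (log axis) of 8 genes at G1, HU, R30 and R60 in WT (blue) and mec1 (orange), with 1 library per point and lines that join the times of a strain. RNR2 reached 2069 RPM in WT HU and 310 RPM in mec1 HU.

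Which genes differed between cells held in G1 by pheromone and cells in hydroxyurea was compared over both strains. Of 25 pheromone response genes, 21 fell and 4 were not called. AGA1, which encodes the anchor of the a-agglutinin (chromosome XIV, 703699 to 705876), went from 1291 to 45.9 RPM in WT and from 1076 to 65.0 RPM in mec1, with a fitted change of −4.41 (SE 0.21, log2). MFA1, which encodes the a-factor pheromone, changed by −4.30, the protease gene BAR1 by −3.78 and the signalling regulator gene SST2 by −3.07. Genes that rose included the low-affinity glucose transporter gene HXT1 (3.92, SE 0.45), the mitotic cyclin gene CLB1 (3.21), the cell wall mannoprotein gene TIR1 (3.13, SE 0.17) and the glyceraldehyde-3-phosphate dehydrogenase gene TDH1 (3.05). The limma test with Benjamini-Hochberg adjustment gave adjusted p = 0.000497 for AGA1, MFA1, SST2 and TIR1, 0.00706 for BAR1, 0.00809 for HXT1, 0.0109 for CLB1 and 0.0346 for TDH1. It called 591 of 6504 features, 297 higher and 294 lower in HU.

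Adjusted over the list alone, 23 of the pheromone response genes fell. The fitted changes of FIG2, PRM1 and FIG1 were −3.16, −3.20 and −2.80, and the list's adjusted p was 1.69e-20 (camera in limma, Benjamini-Hochberg), against adjusted p = 0.707 with an estimated correlation. Of 18 oxidative stress genes, targets of the transcription factor Yap1, 10 rose, among them PRX1 (1.81), CCP1 (1.80) and TRX2 (1.74). Adjusted over the list alone, 15 rose (adjusted p = 2.77e-10 by camera in limma with Benjamini-Hochberg adjustment, adjusted p = 0.749 with an estimated correlation). Of 22 amino acid biosynthesis genes, 5 rose, ILV6 (1.62) among them. Adjusted over the list alone, 15 rose and 1 fell (adjusted p = 9.05e-08 by camera in limma with Benjamini-Hochberg adjustment, adjusted p = 0.753 with an estimated correlation). Of 34 nuclear respiratory chain and ATP synthase genes, 18 fell, CYC1 by 1.49 and QCR7 by 1.22 among them, and 23 fell adjusted over the list alone. That list had adjusted p = 4.93e-10 by camera in limma with Benjamini-Hochberg adjustment, and adjusted p = 0.749 with an estimated correlation. Glycolysis genes rose in 8 of 16 cases, ENO1 by 2.26, and in 11 adjusted over the list alone. Their adjusted p of 1.73e-05 (camera in limma, Benjamini-Hochberg) became 0.265 after quantile normalization, and adjusted p = 0.749 with an estimated correlation.

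In the ribosomal protein list, which also holds the RNase P subunit gene RPP1, 15 of 138 genes fell, RPL24A by 0.92 and RPS7B by 0.87, and in 56 adjusted over the list alone. Ribosome biogenesis genes fell in 2 of 38 cases, BRX1 by 0.63 and RLP7 by 0.48, and in 11 adjusted over the list alone. The adjusted p-values of these lists were 2.91e-16 and 6.52e-06 (camera in limma, Benjamini-Hochberg), and for both adjusted p = 0.753 with an estimated correlation. Among 20 DNA damage induced genes, HUG1 rose by 2.34 and 19 were not called, with 6 higher and 1 lower adjusted over the list alone (adjusted p = 0.0112 by camera in limma with Benjamini-Hochberg adjustment, adjusted p = 0.753 with an estimated correlation). RNR2, RNR3 and RNR4 had fitted rises of 2.15, 2.07 and 1.83 without being called. Their SEs were 0.60, 0.64 and 0.58, against 0.16 for HUG1. The model counts uneven strains as spread, and these 3 rose by 3.10 to 3.53 in WT and by 0.55 to 1.01 in mec1. With neighbours separated, HUG1 rose by 8.96 in WT and 4.55 in mec1, from 0 and 0.16 RPM in G1. Among 18 G2/M genes, CLB1 and the mitotic cyclin gene CLB2 (1.91) rose, with 5 higher and 1 lower adjusted over the list alone (adjusted p = 0.00508 by camera in limma with Benjamini-Hochberg adjustment, adjusted p = 0.804 with an estimated correlation). Among 21 ergosterol genes, 4 fell, ERG6 by 0.88 and HMG1 by 0.78 among them, and ERG4 rose by 0.75, with 9 lower and 1 higher adjusted over the list alone. The list's adjusted p was 0.000999 (camera in limma, Benjamini-Hochberg), against adjusted p = 0.753 with an estimated correlation.

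Upward shifts also passed for 32 proteasome genes (adjusted p = 0.00169, median change 0.22), 25 general stress genes (0.0176, median 0.20), 19 sulphur assimilation genes (0.0321, median 0.25) and 15 seripauperin genes, which are near-identical copies (0.0306, median 0.42), all by camera in limma with Benjamini-Hochberg adjustment. None of them passed at adjusted p = 0.829, 0.753, 0.749 and 0.753 with an estimated correlation, and after quantile normalization the general stress and seripauperin lists had adjusted p = 0.0531 and 0.185. Called genes in them were GLC3 (0.99), MET17 (0.83), MET22 (0.79) and MMP1, which fell by 1.09, and adjusted over the list alone 3 sulphur genes rose, 1 fell, and 0 of the other 3 lists passed. The lists that did not pass with camera in limma (Benjamini-Hochberg) were G1/S genes (adjusted p = 0.249), histone genes (0.746), M/G1 genes (0.40), checkpoint kinases and adaptors (0.743), alpha mating type genes (0.571), meiosis genes (0.320), the iron regulon (0.0953), copper homeostasis (0.751), heat shock genes (0.0826, and 0.0469 after quantile normalization), phosphate starvation (0.229), hexose transporters (0.745) and strain markers (0.861). The checkpoint list had a mean change of 0.12 and a median of −0.05, and the strain marker list a mean of −0.27 and a median of 0.24.

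Several called features lie in the windows of a gene with a larger change: YHR095W next to HXT1, YGR107W next to CLB1, and MRPL28 and TFB3 next to MFA1. HOP2 lies next to AGA2, whose fitted change of −1.89 was smaller than that of HOP2 (−3.88). With neighbours separated, however, HOP2 had 0 RPM in G1 and 17.7 (WT) and 12.4 RPM (mec1) in HU, a change of 3.99. Its fall in the deposited values was therefore not kept. The count of 591 depends on the libraries that set the spread: it was 218 without the R30 libraries and 227 with only the 4 libraries of the times compared.

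The change from hydroxyurea to 30 min after its removal was compared next. ACO1, which encodes the aconitase of the citric acid cycle (chromosome XII, 735214 to 737550), went from 51.7 to 529 RPM in WT and from 45.6 to 1241 RPM in mec1, a fitted rise of 4.03 (SE 0.42). IDH2, a subunit of isocitrate dehydrogenase, rose by 2.81, the mitochondrial NADH dehydrogenase gene NDE1 by 1.81 and HAP4, the activator of respiratory genes, by 1.26. HXT1 changed by −3.60, the enolase gene ENO1 by −2.71, the peroxidase genes GPX2 and CCP1 by −2.42 and −1.88, and the sulfiredoxin gene SRX1 by −1.63. In limma with Benjamini-Hochberg adjustment, ACO1, NDE1, GPX2 and SRX1 had adjusted p = 0.0196, CCP1 0.0232, ENO1 0.0243, IDH2 0.0257, HXT1 0.0286 and HAP4 0.0485. The test called 56 features, 18 higher and 38 lower at R30.

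Oxidative stress genes fell in 8 of 18 cases, among them TRR1 by 1.47 and TSA1 by 1.13, and in 12 adjusted over the list alone (adjusted p = 4.76e-15 by camera in limma with Benjamini-Hochberg adjustment, adjusted p = 0.737 with an estimated correlation). Glycolysis genes fell in 5 of 16 cases, among them TDH2 by 1.05 and TPI1 by 1.02, and in 10 adjusted over the list alone (adjusted p = 2.6e-10 by camera in limma with Benjamini-Hochberg adjustment, adjusted p = 0.707 with an estimated correlation). Ergosterol genes had 21 of 21 positive changes, of which 0 were called over all genes and 14 adjusted over the list alone. Respiratory chain genes had 1 called, QCR7 (0.96), and 12 adjusted over the list alone. Of the 18 G2/M genes, 0 were called over all genes and 6 rose adjusted over the list alone. These lists had adjusted p = 1.29e-08, 1.03e-06 and 1.34e-06 by camera in limma with Benjamini-Hochberg adjustment, and adjusted p = 0.737, 0.753 and 0.753 with an estimated correlation. Shifts also passed upwards for histone genes (adjusted p = 0.00787, median 0.74), ribosomal protein genes (0.00103), ribosome biogenesis (0.0243, and 0.0914 after quantile normalization) and the proteasome (0.00621), and downwards for G1/S genes (0.00597), by camera in limma with Benjamini-Hochberg adjustment. The same lists had adjusted p = 0.753, 0.900, 0.832, 0.843 and 0.832 with an estimated correlation, and 0 of their members were called over all genes, with 1 histone gene higher and 1 G1/S gene lower adjusted over the list alone.

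STT4 lies next to ACO1 and YHR095W next to HXT1. Among the named genes, COQ6, GPT2, ISW1, SIA1, BAG7 and SPO16 changed sign when neighbours were separated. SPO16, next to SPO12, then had at most 4.01 RPM in any library. The count of 56 was 28 without the G1 libraries, 3 in limma without the mean-dependent prior, and 17 with only the 4 libraries compared.

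At 60 min, expression was compared with both earlier states. Against HU, ACO1 rose by 3.49 (adjusted p = 0.0205, limma with Benjamini-Hochberg adjustment), the cell wall mannoprotein gene TIP1 (chromosome II, 372100 to 372732) by 2.40 (0.00127) and the secreted mannoprotein gene HSP150 by 1.81 (0.0088). ENO1 changed by −2.93, HXT1 by −3.19 and the thioredoxin gene TRX2 by −1.63 (adjusted p = 0.0174, 0.0322 and 0.0322, limma with Benjamini-Hochberg adjustment). TIP1 was at 112 RPM in WT HU and 539 RPM in WT R60, and at 89.6 and 530 RPM in mec1. Against G1, AGA1 changed by −3.95 (0.00224) and MFA1 by −2.94 (0.00422), while the plasma membrane protein genes MRH1 and NCE102 rose by 2.88 (0.0116) and 2.69 (0.0185), the secreted glycoprotein gene YGP1 by 2.32 (0.00978) and CLB1 by 2.74 (0.0300), all adjusted p-values of limma with Benjamini-Hochberg adjustment. Against HU, 62 features were called (19 higher, 43 lower), and against G1, 103 (43 higher, 60 lower).

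Against HU, oxidative stress genes fell in 7 of 18 cases (14 adjusted over the list alone) and glycolysis genes in 5 of 16 (11 adjusted over the list alone). Respiratory chain genes rose in 2 of 34 cases, QCR7 (1.27) and QCR2 (0.94), and in 20 adjusted over the list alone. The lists had adjusted p = 5.72e-15, 1.8e-13 and 3e-13 by camera in limma with Benjamini-Hochberg adjustment, and adjusted p = 0.737, 0.707 and 0.737 with an estimated correlation. The 24 M/G1 genes act in daughter cell separation, replication licensing and entry into the cell cycle, among other steps. They had 24 positive changes, of which 0 were called over all genes and 12 adjusted over the list alone, and ergosterol genes had 0 and 11 (adjusted p = 3.3e-08 and 1.22e-06 by camera in limma with Benjamini-Hochberg adjustment, adjusted p = 0.753 and 0.737 with an estimated correlation). The cell wall gene PIR1 had a fitted change of 4.61 and the cell separation gene EGT2 one of 2.93 without being called. G1/S genes (adjusted p = 0.00395) and ribosomal protein genes (0.00916) shifted upwards, and DNA damage induced genes (0.00257) and copper homeostasis genes (0.0488, and 0.118 after quantile normalization) downwards, by camera in limma with Benjamini-Hochberg adjustment, with 0 members called over all genes. They had adjusted p = 0.831, 0.905, 0.753 and 0.753 with an estimated correlation, and adjusted over the list alone 1 G1/S gene rose and 1 fell, and 2 DNA damage and 2 copper genes fell.

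Against G1, pheromone response genes fell in 18 of 25 cases and in 23 adjusted over the list alone. Amino acid biosynthesis genes rose in 2 of 22, ILV6 (1.27) and ASN1 (1.15, named after its value was seen), and in 19 adjusted over the list alone. Among 18 G2/M genes CLB1 rose (7 adjusted over the list alone). Among 24 M/G1 genes the replication licensing gene CDC6 rose by 1.64 (11 adjusted over the list alone). The lists had adjusted p = 3.66e-27, 3.65e-10, 1.12e-06 and 0.000219 by camera in limma with Benjamini-Hochberg adjustment, and adjusted p = 0.707, 0.753, 0.753 and 0.753 with an estimated correlation. The sulphur list, with the sulphite reductase gene MET10 (1.16) called and 3 genes higher adjusted over the list alone, had adjusted p = 0.000779 (camera in limma, Benjamini-Hochberg) and adjusted p = 0.707 with an estimated correlation. With 0 members called over all genes, ribosomal protein genes (adjusted p = 2.41e-15), ribosome biogenesis (3.35e-08) and glycolysis (0.0209, and 0.127 after quantile normalization) shifted downwards, and G1/S genes (3.9e-05), the proteasome (0.000236) and general stress genes (0.00885) upwards, by camera in limma with Benjamini-Hochberg adjustment. Their values in the same order were adjusted p = 0.753, 0.753, 0.753, 0.804, 0.824 and 0.753 with an estimated correlation, and adjusted over the list alone 2 G1/S genes rose and 0 members of the other lists passed.

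Both counts move with the libraries used: that against HU was 4 without the R30 libraries, 32 without the G1 libraries and 194 with only the 4 libraries compared, and that against G1 was 53 without the R30 libraries. Among the named genes, separating neighbours turned the sign of COQ6 and SPO16 against HU and of HOP2 against G1.

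The strains were compared over the 4 times. SML1, which encodes an inhibitor of RNR (chromosome XIII, 159383 to 159697), was at 245, 453, 845 and 310 RPM in WT and at 21.3, 58.0, 65.5 and 39.6 RPM in mec1, a fitted difference of −3.25 (SE 0.15, limma with Benjamini-Hochberg adjusted p = 0.000391). Its neighbour HUG1 (158760 to 158966) differed by −3.39 (SE 0.11, limma with Benjamini-Hochberg adjusted p = 9.14e-05), but in G1 its neighbour-separated value was 0 RPM in WT and 0.16 RPM in mec1. The histidine biosynthesis gene HIS3, a common selection marker, was higher in mec1 by 1.68 (SE 0.17, limma with Benjamini-Hochberg adjusted p = 0.0104), and CKS1, a subunit of the cyclin-dependent kinase complex that lies next to MEC1, by 1.34 (SE 0.09, limma with Benjamini-Hochberg adjusted p = 0.00201). Others lay on chromosome V around GLC7 (432491 to 433954), which encodes protein phosphatase 1 (GLC7, YER133W-A, YER134C, YER135C, YER137C and YER137W-A higher by 1.09 to 1.51, YER137C-A, YER138C, YER138W-A and YER139C lower, at −3.95 to −0.99), or next to HIS3 or SML1 (YOR203W 1.22, YML057C-A −1.67). The test called 18 features, 11 higher and 7 lower in mec1, with 1758 at an unadjusted p under 0.05. Leaving out 1 time changed the count to 669 (without G1), 7 (without R30) or 7 (without R60).

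**Figure D2:**
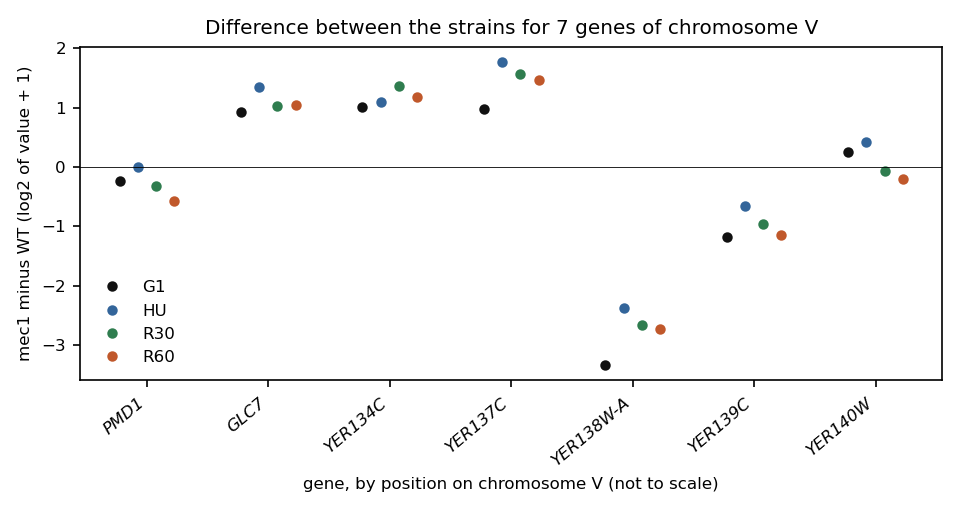
Differences between the strains (mec1 minus WT, log2 of value + 1) of 7 genes by their position on chromosome V, not to scale, with 1 point per time in the colours given. GLC7, YER134C and YER137C lie between 0.93 and 1.77 at every time and YER138W-A at −2.38 or lower, while PMD1 and YER140W, on either side, lie between −0.57 and 0.42 in these deposited values. With neighbours separated, YER140W had 1.27, 2.46, 0.21 and 0.30 at G1, HU, R30 and R60.

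Heat shock genes had positive strain differences in 20 of 20 cases and proteasome genes in 32 of 32, and ribosomal protein genes had 6 positive differences out of 138. Over all genes 0 members of these lists were called by limma, and adjusted over the list alone 14 heat shock and 12 proteasome genes were higher and 68 ribosomal protein genes lower in mec1. The largest heat shock differences were those of the disaggregase gene HSP104 (1.69) and of BTN2 (1.47), each with a limma Benjamini-Hochberg adjusted p of 0.0996. The lists had adjusted p = 5e-06, 6.57e-07 and 5.36e-42 by camera in limma with Benjamini-Hochberg adjustment, and adjusted p = 0.753 for each with an estimated correlation. General stress genes (adjusted p = 0.00559, 8 higher adjusted over the list alone), ergosterol genes (0.00597, 0) and seripauperins (0.0438, 2, and 0.0924 after quantile normalization) shifted upwards by camera in limma with Benjamini-Hochberg adjustment, each with adjusted p = 0.753 with an estimated correlation. Amino acid biosynthesis (adjusted p = 3.88e-05, 3 lower adjusted over the list alone, and 0.127 after quantile normalization), ribosome biogenesis (0.000779), M/G1 genes (0.00707), glycolysis (0.0117, and 0.938 after quantile normalization) and pheromone response genes (0.0128) shifted downwards by camera in limma with Benjamini-Hochberg adjustment. They had adjusted p = 0.753, 0.799, 0.824, 0.753 and 0.753 with an estimated correlation.

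**Figure D3:**
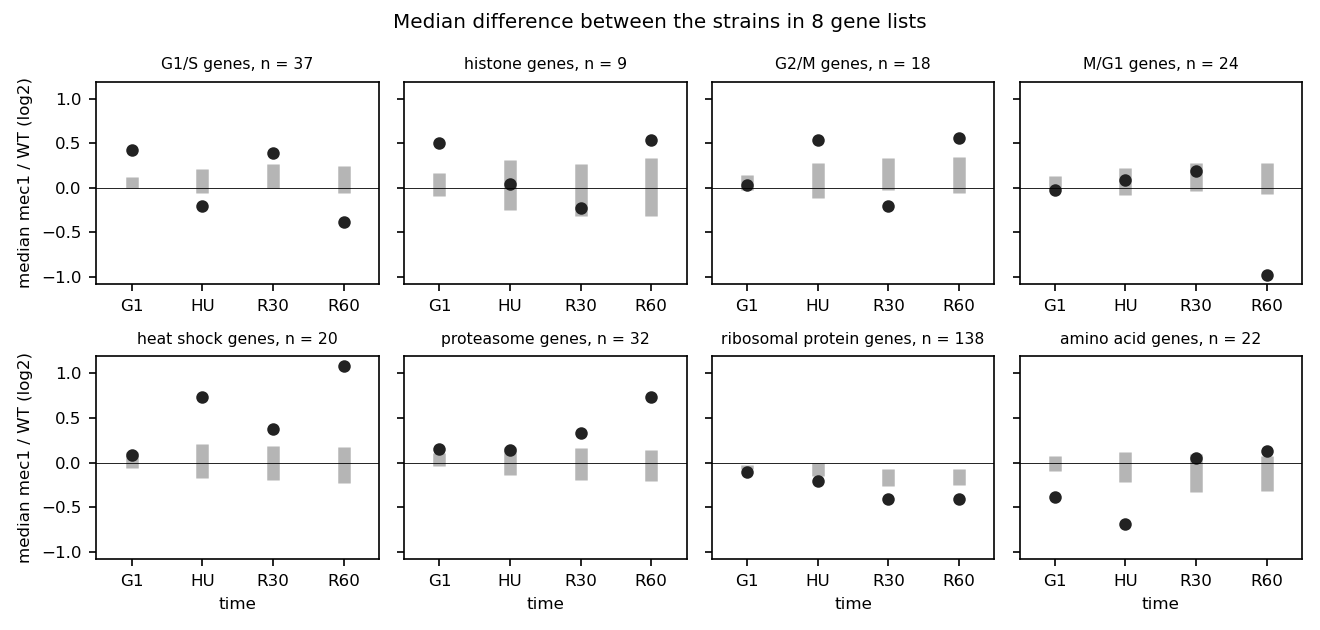
Median difference between mec1 and WT libraries (log2) in 8 gene lists at each time (black points), with the central 95% of the medians of matched random lists (grey bars). At R60 the medians were 1.09 for heat shock genes, 0.74 for proteasome genes and −0.98 for M/G1 genes.

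Time by time, 41 features differed by 2-fold or more between the strains in G1 (26 higher in mec1, 15 lower), 435 in HU (337 and 98), 287 at R30 (258 and 29) and 311 at R60 (228 and 83). These are differences between single libraries, with no replicate check. Under quantile normalization the splits at R30 and R60 were 134 to 54 and 129 to 118. The median of all genes lay at 0.13 and 0.10 under the deposited scale, so lists are given with matched random lists. In G1 the 37 G1/S genes had a median difference of 0.43 and the 9 histone genes one of 0.51, each above all 10000 random lists (percentile 100). In HU the G2/M genes had one of 0.54 (percentile 100). At R60 the M/G1 genes had a median of −0.98 (percentile 0), with 11 of 24 lower by 2-fold or more. Of the M/G1 genes, the chitinase gene CTS1 was at 521 RPM in WT R60 and 101 RPM in mec1 R60, and EGT2 at 400 and 81.0 RPM. The G1 cyclin gene CLN2, which is in the G1/S list and not in the M/G1 list, was at 132 and 36.2 RPM in the same libraries. Heat shock genes had a median of 1.09 at R60, with 20 of 20 higher in mec1 and 11 by 2-fold or more. Proteasome genes had a median of 0.74 with 32 of 32 higher (both percentile 100).

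Whether the strains responded differently to hydroxyurea was asked by subtracting the WT change from the mec1 change, which has no test. RNR1, the large RNR subunit gene (chromosome V, 298948 to 301614), changed by 2.70 from G1 to HU in WT and by −0.87 in mec1, a difference of −3.57 (95% counting interval −3.87 to −3.27). It was at 86.9 RPM in WT G1 and already at 181 RPM in mec1 G1. RNR2 changed by 3.53 and 0.77, RNR4 by 3.10 and 0.55, and RNR3 by 3.13 and 1.01, from 13.99 to 130 RPM in WT and from 14.3 to 29.9 RPM in mec1. TOS4, a G1/S gene whose product has a forkhead-associated domain, changed by 2.09 and −0.73, and TDH1 by 4.25 and 1.86. In the other direction, SPF1, an ATPase of the endoplasmic reticulum, changed by −1.15 in WT and 1.35 in mec1, HSP104 by −0.81 and 1.67, AVL9 by −1.98 and 0.49, and the sulphite reductase gene ECM17 by −1.58 and 0.73. The WT falls rest on WT HU, the library with the fewest reads. At G1, HU, R30 and R60 in WT, SPF1 was at 129, 57.3, 156 and 152 RPM. AVL9 was at 35.1, 8.14, 39.1 and 36.5 RPM and ECM17 at 53.4, 17.2, 71.0 and 98.0 RPM. HSP104 was at 46.8 RPM in WT HU and also at 47.6 RPM in WT R60. Features near RNR2 (YJL026C-A, YJL027C, YJL028W, RRN7) and RNR4 (OKP1) were among the 10 with the lowest difference, and those of RRN7 (4.73) and OKP1 (0.60) were positive and that of YJL028W 0 when neighbours were separated. OKP1 then had at most 4.14 RPM in any library and YJL028W 0.

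The responses of the strains from G1 to HU correlated at 0.64 across genes, which are not independent replicates. There, 415 features differed by 2-fold or more (318 higher in mec1, 97 lower). From HU to R30 the correlation was 0.42 with 337 features (252 and 85, or 188 and 115 after quantile normalization). From HU to R60 it was 0.36 with 407 (259 and 148). G1/S genes had a median of 0.40 from G1 to HU in WT and −0.18 in mec1, a median difference of −0.59 with 6 of 37 positive. Histone genes had a difference of −0.74 (both percentile 0). Both lists started higher in mec1 G1, and in HU their median differences between the strains were −0.21 and 0.04. The median difference was 0.44 for G2/M genes (percentile 99.9), and 0.54 for heat shock genes and 0.63 for pheromone response genes (both percentile 100). Pheromone response genes started lower in mec1 G1, with a median difference between the strains of −0.34 there and 0.14 in HU. DNA damage induced genes had a median of 0.56 in WT and 0.38 in mec1, with a median difference of −0.30 (percentile 0.03).

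**Figure D4:**
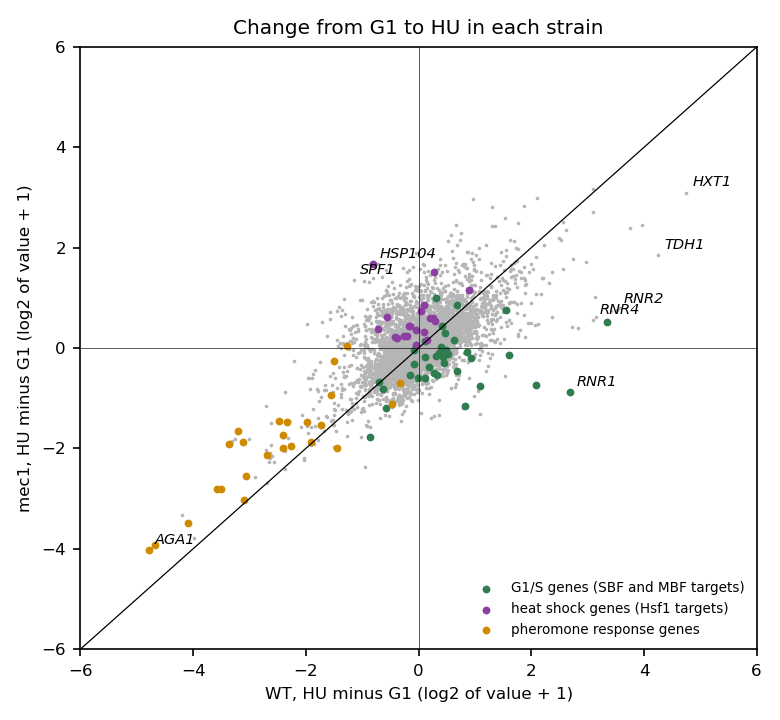
Change from G1 to HU (log2 of value + 1) in mec1 against that in WT, with 1 point per feature, members of 3 gene lists in colour and a line where both strains change alike. RNR1 lies at 2.70 in WT and −0.87 in mec1, and HSP104 at −0.81 and 1.67.

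Within WT, 495 features differed by 2-fold or more between HU and G1 (293 higher, 202 lower), 322 between R30 and HU (99 and 223), 341 between R60 and HU (167 and 174) and 286 between R60 and G1 (170 and 116). Within mec1 the counts were 456 (306 and 150), 156 (87 and 69), 180 (108 and 72) and 474 (362 and 112). After quantile normalization the last 3 were split 81 to 87, which turns the direction, 98 to 93 and 257 to 154. RNR2 went from 2069 RPM in HU to 569 at R30 and 280 at R60 in WT. In mec1 it stood at 310, 305 and 253 RPM. RNR1 went from 568 to 62.2 and then 338 RPM in WT, and was at 98.5, 69.9 and 109 RPM in mec1. CLB2 was highest at R30 in WT (106 RPM) and in HU in mec1 (94.0 RPM).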

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

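The tests on the parts of the RNR pattern, the test of depth and all neighbour-separated values were chosen only after the result was seen. Only the genes named for the strain difference of the HU response, the 10 largest in each direction, were searched for changes of opposite sign. Of these, 10 had changes of opposite sign from G1 to HU in the strains, beyond counting error, and were picked out for that reason. Naming genes by the size of the difference favours opposite signs, and the other features were not searched. The difference between the strains (mec1 minus WT, log2) was not tested for any of the 10 genes, since there is 1 library per group.

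Those higher in mec1 included HSP104, the disaggregase gene, with a difference of 2.48 (95% counting interval 2.06 to 2.91), and SPF1, an ATPase of the endoplasmic reticulum, with 2.502 (2.13 to 2.87). AVL9, which acts in exocytic transport, differed by 2.47, and the sulphite reductase gene ECM17 by 2.30. YEL030C-A, a feature near SPF1, differed by 2.30. The vacuolar calcium pump gene PMC1 differed by 2.11, EAP1, which encodes a binding protein of the translation factor eIF4E, by 1.99 and the kinase gene KIN3 by 1.956. With neighbours separated the directions stayed opposite for SPF1, HSP104, AVL9, ECM17, PMC1 and EAP1, while KIN3 had 0.39 in WT and 5.10 in mec1, and YEL030C-A was not measured there.

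Those lower in mec1 were RNR1 (−3.57) and TOS4 (−2.82), part of a wider pattern in which RNR and G1/S genes had a smaller or no increase in mec1 HU, and part of it lies in G1, where the G1/S median was already higher in mec1 by 0.43 (−0.21 in HU) and RNR1 was at 181 RPM against 86.9 RPM in WT. Shared windows can account for part of the 10 genes with the lowest difference, since 6 of them kept a difference of −1 or lower with neighbours separated. Of these 6, TOS4 did so from 0 RPM in mec1 at both times. YJL026C-A, also among the 10, had no separated value and could not be judged. The weakest of RNR1, RNR2, RNR4 and TDH1 was then −2.48, which argues against shared windows for these 4, whereas RRN7 had 4.73, as shared windows would give, and OKP1 and YJL028W had too little separated signal to tell. Lower depth of the WT HU library was argued against for RNR1 to RNR4 by their counting bound nearest to 0, −1.40. Another position in the cell cycle of the mec1 cells at the HU time is consistent with the median difference of 0.44 for G2/M genes, and it stays open beside a role of Mec1 itself, which these libraries do not separate.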

How the results depend on the processing

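The neighbour-separated values and the deposited values of the same genes were chosen after seeing the data. Quantile normalization kept 20 of 21 counts within 1.5 times of their value, a pseudocount of 0.1 kept 19 of 20, and dropping the filter or the 10 genes with the highest mean moved 0 of 5 tested counts beyond that. Of 97 changes of named genes, 93 kept their direction and side of the threshold under quantile normalization, 67 without the mean-dependent prior and 47 at a threshold of 0.01.

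At a threshold of 0.01 the counts were 66 (HU versus G1), 1 (R30 versus HU), 3 (R60 versus HU) and 30 (R60 versus G1), because the threshold is stricter. Without the mean-dependent prior they were 3 for R30 versus HU and 32 for R60 versus HU. With only the 4 libraries compared and 1 residual degree of freedom, they were 227 (HU versus G1), 17 (R30 versus HU) and 194 (R60 versus HU). Leaving out a time in turn gave 218 to 443 for HU versus G1, 28 to 45 for R30 versus HU, 4 to 32 for R60 versus HU, 53 to 114 for R60 versus G1 and 7 to 669 for mec1 versus WT. The cause was not tested.

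With neighbours separated the counts were 296, 24, 29 and 53 for the same time contrasts and 8 for mec1 versus WT. The deposited values of the same genes gave 480, 41, 49, 95 and 10. Of the 591 calls in HU versus G1, 209 were also called with neighbours separated, 202 of them in the same direction. Single-library counts of 2-fold differences rose to 1025, 850, 799 and 678 in WT (HU over G1, R30 over HU, R60 over HU, R60 over G1), 925, 511, 571 and 901 in mec1, and 301, 774, 712 and 743 between the strains at G1, HU, R30 and R60. The strain differences had 904, 922 and 955. Between the strains, the G1 count was 74 with a pseudocount of 0.1, and the R30 count was 188 after quantile normalization. The cause was not tested.

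Among the named genes, some signs turned with neighbours separated. In HU versus G1 they were those of HOP2 (3.99) and TFB3 (5.25). In R30 versus HU they were those of SIA1 (−0.15), BAG7 (−0.027), COQ6 (2.10), GPT2 (0.072) and ISW1 (1.15). COQ6 (2.26) turned in R60 versus HU and HOP2 (3.60) in R60 versus G1. In the untested strain difference, RRN7 (4.73) and OKP1 (0.60, with at most 4.14 RPM in any library) turned. Over all called features in the separated test, 441 of 497 kept their sign in HU versus G1. In R30 versus HU, R60 versus HU and R60 versus G1 the numbers were 38 of 47, 45 of 53 and 82 of 92. MEC1, which the separation does not resolve, turned from 0.99 to −0.064 in HU versus G1 and, without being called, to 1.32 in R30 versus HU and 0.47 in R60 versus HU. SPO16, left out of the separated test by its low values, turned to −1.16 in R30 versus HU and −0.71 in R60 versus HU. The cause was not tested.

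Of 130 list tests, 55 passed with the preset correlation, 0 with an estimated one and 5 with fry, which tests whether a list's genes move one way and compares no lists. The 5 were pheromone response genes in HU and in R60 versus G1, sulphur assimilation in R60 versus G1, and glycolysis in R30 and in R60 versus HU. With the estimated correlation the lowest adjusted p was 0.707 (camera in limma, Benjamini-Hochberg), so that setting decides neither for nor against any list. Depth limits the single pairs most where WT HU enters. Alternatives that need counts per gene (DESeq2, voom, RLE factors, library totals, thinning, prior counts) were not run, because the values are window means. The table holds no mitochondrially encoded genes, so leaving those out changes nothing.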

Other observations

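The tests of missing induction by hydroxyurea, the splits of the libraries, the tests of window sharing at single times of SML1 and HUG1, those of window sharing and of an extra copy on chromosome V and all neighbour-separated values were chosen only after the result was seen.

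Further gene groups had unlike values in the strains during recovery from hydroxyurea. Amino acid biosynthesis genes, targets of the activator Gcn4, had a median change from HU to R60 of −0.37 in WT and 0.51 in mec1, and the strain difference was positive for 21 of 22 with a median of 0.77 (percentile 100 among random lists). Part of that lies in HU, where their median was lower in mec1 by 0.69, against a difference of 0.14 at R60. From HU to R30, G2/M genes had a median of 1.11 in WT and 0.18 in mec1, with a strain difference of −0.90 (percentile 0). Much of that lies in HU, where their median was higher in mec1 by 0.54, against −0.20 at R30. DNA damage induced genes had a median from HU to R60 of −0.46 in WT and 0.06 in mec1, from a strain difference of −0.20 in HU to one of 0.25 at R60. These differences rest on 1 library per strain and time and were not tested.

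Of 28 iron regulon genes, 4 rose, 2 fell and 22 were not called from G1 to HU, and the list did not pass (camera in limma, Benjamini-Hochberg adjusted p = 0.0953, and adjusted p = 0.753 with an estimated correlation). The cell wall mannoprotein gene FIT3, which helps retain siderophore iron, rose by 1.86 and the reductase gene FRE5, its neighbour, by 1.38 (0.035 with neighbours separated), while the haem oxygenase gene HMX1 fell by 1.13 (limma with Benjamini-Hochberg adjusted p = 0.0115, 0.0131 and 0.0223). The others called, named after their values were seen, were COT1 (1.01), VHT1 (0.78) and FET3 (−0.86). FIT3 was at 84.2 RPM in WT G1 and 280 RPM in WT HU, and at 64.3 and 260 RPM in mec1. YGR109W-B, which encodes the gag-pol protein of the retrotransposon Ty3, was at 81.0 RPM in WT G1 and 12.8 RPM in WT HU, and at 60.2 and 11.7 RPM in mec1.

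In the deposited values SML1 and HUG1 were lower, and HIS3 and CKS1 higher, in mec1 at all 4 times. Shared windows were argued against for SML1 at all times and HUG1 at HU, R30 and R60 (weakest separated difference −2.85), but not for HUG1 in G1, which had next to no separated signal in either strain (difference 0.22) and which its mean of −2.87 hides. Hydroxyurea alone was argued against for SML1, which already differed by −4.39 in G1, and stays open for HUG1. HUG1 went from a separated value of 0 RPM in WT G1 to 498 RPM in WT HU (8.96 as log2 of value + 1) and from 0.16 to 26.3 RPM in mec1 (4.55), so a smaller induction is open. A fully missing one is not what the separated mec1 values show, but these assume an SML1 transcript at its R64 position. The deposited values of both neighbours rose in mec1 from G1 to HU, HUG1 from 7.67 to 37.7 RPM and SML1 from 21.3 to 58.0 RPM, so induction of HUG1 in mec1 is not established. A candidate explanation is that the mec1 strain lacks SML1, as strains without MEC1 often do, with HIS3 as the marker, but its separated SML1 value reached 13.7% of WT and the labels do not give that genotype, so this cannot be told apart from low expression. Whether the coding sequence of MEC1 is absent cannot be told either: its separated value of 53.8 to 59.3 RPM in mec1 exceeded WT at all 4 times, but WT, which carries the gene, had at most 5.31 RPM, so WT gives no level to compare with.

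On chromosome V, GLC7, YER134C and YER137C were higher in mec1 in the deposited values. The Ty1 feature YER138C, and YER138W-A beyond its end, were lower. Shared windows were argued against for GLC7, YER134C and YER137C by their smallest separated difference, 1.09, while YER135C had no separated signal. The separated difference of YER138C was 0 at all 4 times (deposited −4.09 to −3.29), so shared windows stay open for it. YER138W-A kept a mean separated difference of −3.87 and YER139C one of −0.59. Reads shared between Ty1 copies were argued against by the median difference of 0.18 over the other Ty features. An extra copy of a segment with GLC7, YER134C and YER137C in the mec1 strain would give about 1. The median separated difference of the 3 in G1 (1.02) and the 0.93 to 1.37 of GLC7 and YER134C over the times lie near that. However, YER137C had 1.31, 2.23, 1.90 and 1.64 at G1, HU, R30 and R60, so an extra copy stays open. YER140W, beyond the lower features, had separated differences of 1.27, 2.46, 0.21 and 0.30 at the same times, so the end of such a segment is not resolved. DNA was not measured, and other differences between the strains stay open.

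Only 8 splits part the libraries of every time as the strains do, too few for a share under 0.05. The strain split called 18 genes, the highest other split called 0, and 1 of the 8 reached 18.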
